A study of Homo sapiens with 24 samples.

How the data were processed

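RNA bound by an antibody against m6A and its input were sequenced as 50-base single-end reads from polyadenylated RNA of U2OS cells, WT or METTL3 KO, grown with 10 µM BrdU, with or without UVC, and collected after 2 min, per the labels' protocols. The 24 samples (12 IP and 12 input libraries) were placed in 8 groups by genotype, UV and library type, with 3, 4, 3 and 2 IP libraries for WT minus UV, WT plus UV, KO minus UV and KO plus UV. Reads were aligned with TopHat2 2.0.14 to build hg38 per the submitters' processing notes. The peak caller, its threshold, the way replicates and inputs were combined, and the release of the transcript annotation are not given in the sources used here. The deposited files were 4 peak lists, 1 per condition, described as covering all its replicates. Their values have no unit of signal (other): each entry of the deposited lists is a RefSeq transcript accession with the start and end of a peak in bases along that transcript, and the name and score fields are empty. The values themselves point to positions counted from 1 with both ends included. So counted, the narrowest peaks span 100 bases, and 51.8% of the starts end in 1, as for 100-base windows moved by 10 bases. The other starts lie off such a grid, and how they arose is not given in the sources used here. No list held a repeated entry or a peak that overlapped another of the same list.

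Each transcript was matched to a gene symbol and gene coordinates (GRCh38) through a RefSeq gene table. Of 9674 transcripts, 9562 (98.8%) were matched, 112 were not and were left out of gene counts, and 114 carried a copy number after the accession, of which 113 were matched after it was removed. Only 2 genes were represented by more than 1 transcript. A peak was called shared when it overlapped a peak of the other list on the same transcript by at least 1 base. The shares without an overlap in the 2 directions of a pair rest on the same overlaps, so their difference largely follows the list sizes. Shares carry 95% Wilson intervals and differences between shares carry Newcombe intervals, and ratios of shares carry intervals computed on the log scale. All of these cover counting error alone, since peaks on the same transcript are not independent and reads without molecular identifiers are not independent molecules. Peaks of all lists that overlapped were merged into 20811 regions for patterns across lists and Jaccard percentages. As a chance level, the peaks were placed at random on their own transcripts, 100 times for the 4 planned pairs in their planned direction and 5 times for the others. Transcript lengths were taken as the furthest peak end in any list, a lower bound that by itself makes the chance overlap too high. Placement was uniform along the transcript and let placed peaks overlap each other. It therefore ignores any preference of peaks for a part of the transcript, which makes the chance overlap too low. The overlap code was tested on simulated data: with 10%, 30% and 50% of the peaks of a list removed and the rest shifted by a few bases, 9.61%, 29.0% and 48.8% were found without an overlap.

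No test between conditions was made, since a condition has 1 list. The comparisons, the named genes and 18 gene lists were fixed before the data were examined. Named genes were ranked by total peak length because the lists have no score. They were the 10 longest with a peak in WT plus UV alone, the 10 longest in WT minus UV alone, the 10 longest in both WT lists and no KO list, the 10 longest in a KO list and no WT list, and the 5 longest in every list. They also included the m6A writers, readers and erasers, and up to 4 members of each other list per comparison and direction and up to 2 in every list, with uncharacterised LOC and LINC genes skipped. The gene lists covered the m6A machinery, nucleotide excision repair, translesion synthesis, the DNA damage checkpoint, p53 targets, immediate early genes, cell cycle and replication, chromatin regulators, ribosomal proteins, ZNF genes, mitochondrially encoded genes, long noncoding RNAs, the osteoblast lineage, heat shock and the unfolded protein response, collagens and matrix, and markers of blood, epithelial and neuronal cells. XPC and DDB2 belong to both the excision repair and the p53 list, and BTG2 to both the p53 and the immediate early list. The mitochondrial list matched 0 symbols of the reference and was not analysed here. The background of a list was the set of genes with a peak in any list, and each count was set beside 10000 random lists of the same size, matched on quintiles of the furthest peak end. Percentiles count ties by their midpoint and were computed for the lists with at least 3 members in that background.

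Alternatives covered the overlap that counts as shared, merging of peaks within 100 bases, genes in place of peaks and bases covered. Added after the data were examined were random thinning of each list to the 9471 peaks of the shortest (100 draws), a minimum width of 150 bases, restriction to transcripts in the compared lists, removal of copy-numbered transcripts, the KO minus UV list alone, the share of peaks at the transcript start (50, 100 or 200 bases) and its settings, the absence of whole transcripts from a list, the ribosomal list without kinases, and the genes found in both lists of a genotype and in neither of the other. Shares by transcript region and by the DRACH motif of the methyltransferase were planned but need coding coordinates and sequence, which were not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.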

Results

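N6-methyladenosine (m6A), a methyl mark on adenosines inside messenger RNA, was mapped by immunoprecipitation of RNA with an antibody against the mark followed by sequencing. The cells were U2OS, a human osteosarcoma line, either wild type (WT) or knocked out (KO) for METTL3, the catalytic subunit of the main nuclear m6A methyltransferase. They were left without UV or exposed to UVC at a dose of 50 J per the labels and collected after 2 min. The 24 samples formed 8 groups. An immunoprecipitated (IP) library and its input were listed 3 times for WT minus UV and 4 times for WT plus UV. For KO minus UV they were listed 3 times, and for KO plus UV 2 times, with replicates labelled 1 and 3. The values analysed were 4 deposited peak lists, 1 per condition for all of its replicates. The lists gave positions on RefSeq transcripts without a score, a read count or a depth, so the depth behind a peak is unknown. There are no replicate values, no difference between conditions could be set against the spread between replicates, and the intervals given are 95% Wilson or Newcombe intervals for counting error alone.

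The WT minus UV list held 13989 peaks on transcripts of 7135 genes, the WT plus UV list 15465 peaks on 7973 genes, the KO minus UV list 13852 peaks on 6967 genes and the KO plus UV list 9471 peaks on 5516 genes. The order of the lists by peak number followed the order by IP libraries, which were 3, 4, 3 and 2. Median peak width was 186 bases in WT minus UV, 189 in WT plus UV, 182 in KO minus UV and 176 in KO plus UV. Noncoding transcripts carried 2.29%, 2.48%, 2.32% and 1.87% of the peaks in the same order. Genes with a peak in every list numbered 3941 of 9559, or 41.2%. Among them, the largest total peak length in WT plus UV was found on KMT2D, a histone H3 lysine 4 methyltransferase (chromosome 12, 49018978 to 49060794, GRCh38), with 18, 12, 14 and 10 peaks in the order above. It was followed by EP300, a histone acetyltransferase, which carried 8 peaks in each list. RNF213 carried 10, 11, 10 and 6 peaks, NOTCH2 carried 8, 8, 8 and 9, and TET3 carried 8, 10, 10 and 6.

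**Figure D1:**
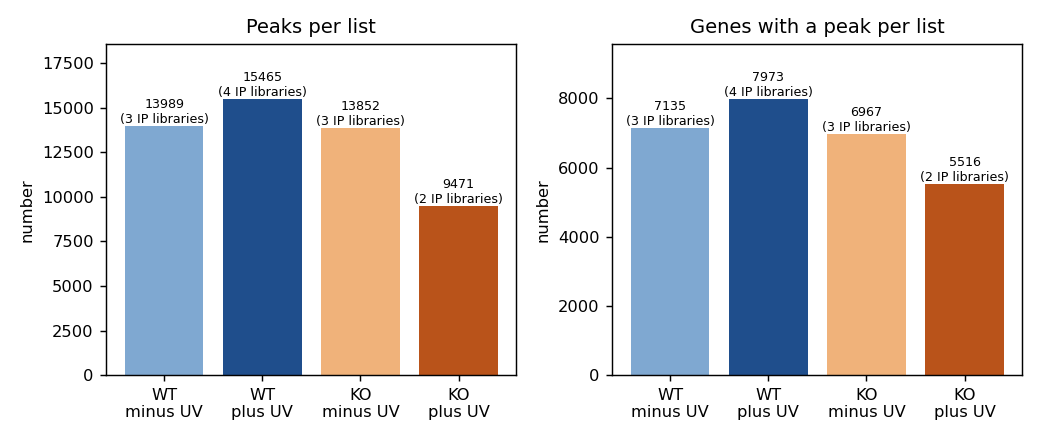
Number of peaks (left) and of genes with a peak (right) in each of the 4 lists, with the number of IP libraries behind each list written above its bar. KO plus UV, with 2 IP libraries, held the fewest of both (9471 peaks and 5516 genes), and WT plus UV, with 4, held the most (15465 and 7973).

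The comparison of WT cells with and without UV addressed whether m6A peaks appear on transcripts within minutes of UV damage. WT plus UV held 1476 more peaks and 838 more genes with a peak than WT minus UV. Of its peaks, 4632 (30.0%, 95% interval 29.2 to 30.7) overlapped no WT minus UV peak, while 3133 WT minus UV peaks (22.4%, 21.7 to 23.1) overlapped no WT plus UV peak. At the gene level, 1661 genes carried a peak with UV alone and 823 without UV alone. Genes with peaks in WT plus UV and in no other list included KDM6A, a histone H3 lysine 27 demethylase (chromosome X, 44873188 to 45112779), with 5 peaks over 1080 bases. TNKS1BP1 (chromosome 11, 57299642 to 57324952) and BAZ1A, a subunit of chromatin remodelling complexes (chromosome 14, 34752731 to 34875360), also carried 5 peaks each. ZBTB24, COL4A1, RGS12, PHC1, ZNF324 and ADAMTSL4 carried between 2 and 5 peaks in that list alone, as did RGPD5, whose listed transcript is numbered as a copy of several and belongs to a family of near-identical genes. Genes with peaks in WT minus UV alone included MCM9, a helicase of homologous recombination repair (chromosome 6, 118813455 to 118935159), with 3 peaks over 1005 bases. UBN2 had 5 peaks, FOXO1, a forkhead transcription factor, had 4, and REV3L, the catalytic subunit of the translesion polymerase zeta (chromosome 6, 111299033 to 111483711), had 4. BAHCC1, ZNF561, SLITRK4, BTBD9, the pseudogene CEP192P1 and ZNF260 carried 3 to 5 peaks in that list alone.

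In WT cells, the excision repair, translesion synthesis and checkpoint groups gained and lost members with UV in numbers within the central 95% of random gene lists of the same size. Of 23 nucleotide excision repair genes with a peak in any list, 17 carried a peak without UV and 18 with it, with 4 gained (4.02 in random lists) and 3 lost (1.99). GTF2H4, RPA3 and GTF2H2 (a copy-numbered transcript) were among those with a peak with UV alone, whereas ERCC4, ERCC8 and CCNH had a peak without UV alone. Of 15 translesion synthesis genes, 13 carried a peak without UV and 11 with it: POLI was gained (2.75 in random lists) and REV3L, SHPRH and HLTF were lost (1.33). Among 28 checkpoint genes, 21 carried a peak without UV and 23 with it, with 5 gained (4.71 in random lists) and 3 lost (2.40). BRCA1, a homologous recombination and checkpoint factor (chromosome 17, 43044295 to 43170327), carried 0 peaks without UV and 6 with it, and CDC25C, TIPIN and HUS1 were also among the 5 gained, while BRCA2, with 3 peaks, ATM and RNF8 were lost. Of 22 p53 targets, 21 carried a peak without UV, against a mean of 16.4 in random gene lists, and 17 with UV. CDKN1A, the cyclin-dependent kinase inhibitor p21, CCNG1, TIGAR and FDXR had a peak without UV alone. These 4 compared with 1.76 in random lists (percentile 93.9). The 21 without UV lay at percentile 99.4, and 0 members were gained with UV against 3.91 in random lists (percentile 0.615). Only 1 member of the list was left without a peak in WT minus UV that UV could add.

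Peaks shared by the WT lists lay close together, with a median distance of 9.5 bases between centres. The 70.0% of WT plus UV peaks with an overlap compared with a mean of 26.7% when peaks were placed at random on the same transcripts. Of the 4632 peaks without an overlap, 2362 (51.0%) lay on transcripts with no WT minus UV peak at all, and on transcripts with a peak in both lists 17.3% of the WT plus UV peaks had no overlap. The UV list came from 4 IP libraries and the other from 3.

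**Figure D2:**
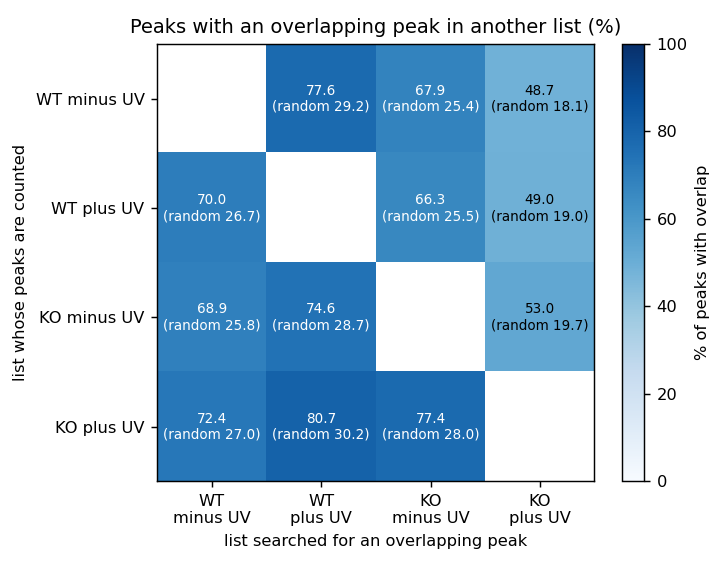
Percent of the peaks of each list (vertical axis) that overlap a peak of each other list (horizontal axis) by at least 1 base, with the mean percent after random placement on the same transcripts in brackets. Observed values run from 48.7% to 80.7%, and the random values from 18.1% to 30.2%.

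In KO cells, the comparison asked whether the same occurs without METTL3. Relative to KO minus UV, the KO plus UV list differed by -4381 peaks and -1451 genes with a peak. The gene difference was -20.8%, and -3.06% after KO minus UV was thinned at random to the size of KO plus UV. Such thinning fixes the number of peaks and does not correct for the number of IP libraries. Of the KO plus UV peaks, 2139 (22.6%, 21.8 to 23.4) overlapped no KO minus UV peak, while 6516 KO minus UV peaks (47.0%, 46.2 to 47.9) overlapped no KO plus UV peak. On transcripts with a peak in both lists 13.4% of the KO plus UV peaks and 2445 of 9781 KO minus UV peaks had no overlap. Losses in the damage response groups were near those of random lists: 7 against 6.74 for the checkpoint, 6 against 5.47 for excision repair, 7 against 5.04 for p53 targets and 2 against 3.52 for translesion synthesis. Among checkpoint genes, 18 carried a peak without UV and 12 with it: MDC1, a mediator of the damage checkpoint with a copy-numbered transcript, was gained with 3 peaks, and BRCA1, TIPIN, RNF168 and ATRIP were among those lost. Excision repair genes with a peak numbered 20 without UV and 14 with it, the members lost including CUL4B, the transcription-coupled repair factors ERCC6 and UVSSA, and ERCC2. ERCC4 and ERCC8, lost with UV in WT cells, were lost in KO cells as well, and CCNH had no KO peak. Of the p53 targets, 17 carried a peak without UV and 11 with it. MDM2, which had 3 peaks in each of the other lists, GADD45A, TIGAR and PLK3 were among the 7 lost, and SESN1 was gained. CDKN1A, TIGAR and FDXR were lost with UV in both genotypes, and CCNG1, lost in WT cells, had no KO peak. Translesion synthesis genes numbered 11 and 9, POLI and USP1 being lost. Of the immediate early genes, 15 of 18 carried a peak in KO minus UV and 17 in KO plus UV, with KLF10 and ATF3 gained and 0 lost against a mean of 4.04 in random lists. ATF3 rested on 1 KO plus UV peak of 100 bases, the smallest width in the lists. KLF10 carried 2 peaks in WT minus UV and 3 in WT plus UV.

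Transcripts with many peaks were often absent from the KO plus UV list. Of the 366 transcripts with at least 5 peaks in KO minus UV, 97 (26.5%, 22.2 to 31.3) carried 0 peaks in KO plus UV. For WT minus UV transcripts with at least 5 peaks, the share without a peak in WT plus UV was 4.97% and in KO minus UV 4.66%. KMT2A, a histone methyltransferase with 8 peaks in KO minus UV, SMARCA2 with 3, CDK6 with 6, ZNF275 with 5 and ZNF445 with 5 had none in KO plus UV. Among transcripts with at least 3 KO minus UV peaks, the share without a KO plus UV peak was 16.9% (13.2 to 21.2) in the shortest quintile of genes by genomic length and 35.8% (30.9 to 41.0) in the longest. The KO plus UV list rested on 2 IP libraries and the KO minus UV list on 3.

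**Figure D3:**
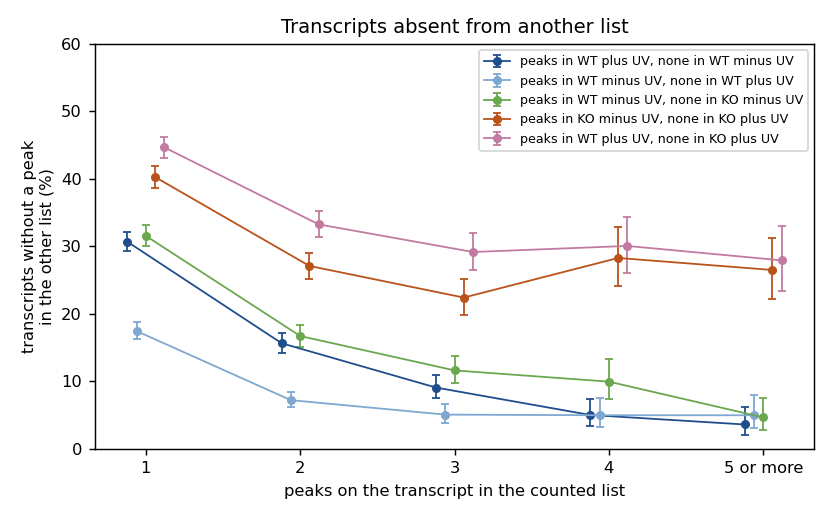
Percent of transcripts that carry no peak in a second list (vertical axis, with 95% Wilson intervals) by the number of peaks they carry in the list counted (horizontal axis), for 5 pairs of lists. At 5 or more peaks, 26.5% and 27.9% of transcripts are absent from KO plus UV, against at most 4.97% in the other 3 pairs.

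WT and KO cells without UV were compared to see which peaks were found with METTL3 present alone. Both lists came from 3 IP libraries, and they held 13989 and 13852 peaks. Of the WT peaks, 4496 (32.1%, 31.4 to 32.9) overlapped no KO peak, and of the KO peaks, 4302 (31.1%, 30.3 to 31.8) overlapped no WT peak, a difference of 1.08 percentage points (-0.0096 to 2.17). Both shares count the same overlaps, whereas the interval of the difference takes them as independent and is a rough guide only. On transcripts with a peak in both lists these shares were 18.3% and 19.8%, and 52.6% of the WT peaks without an overlap lay on transcripts with no KO minus UV peak. At the gene level, 1571 genes carried a peak in WT alone and 1403 in KO alone. Genes with a peak in both WT lists and in no KO list numbered 681, and genes with a peak in both KO lists and in no WT list 191, both counts depending on the KO plus UV list with its 2 IP libraries. The former included NFAT5, a transcription factor of the osmotic stress response (chromosome 16, 69565966 to 69704654), with 7 peaks without UV and 1 with it. RIF1, a factor in double-strand break repair choice and replication timing (chromosome 2, 151409902 to 151534435), had 8 and 6. MYH14 had 6 and 4, PHLPP1, a phosphatase that acts on AKT, had 5 and 5, and DCP2, the mRNA decapping enzyme, had 6 and 3. DOCK3, TNXB, SP4, MAP3K1 and PAN3, a subunit of a poly(A) nuclease, completed the 10 longest. Genes with peaks in KO cells and in no WT list included TTC28 (chromosome 22, 27978014 to 28679840), with 10 peaks in KO minus UV, and GPR158, SLF2, EPHA5, ZNF652, POM121, REL, TLR4 and FAT3, with 2 to 4 peaks there and 0 in KO plus UV. ADAM19, a metalloprotease, carried 4 peaks in KO minus UV and 2 in KO plus UV.

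In most groups the number of members with a peak in a single genotype lay within the central 95% of random gene lists. The exceptions were ZNF genes (62 in WT alone, 41.3 in random lists), the m6A machinery and heat shock genes (0 in WT alone, 2.92 and 3.10 in random lists) and immediate early genes (0 in KO alone, 2.93 in random lists). Of 29 cell cycle genes, 24 carried a peak in WT minus UV and 25 in KO minus UV, with 3 in WT alone (5.05 in random lists) and 4 in KO alone (4.44). KIF11 and TTK, mitotic motor and checkpoint kinase, had a peak in both WT lists and in no KO list, and PLK1, CCNB1, CCNB2 and MKI67 had a peak in both KO lists and in no WT list. Of 30 chromatin regulators, 29 carried a peak in WT minus UV and 25 in KO minus UV; SMARCA4, SUZ12 and KMT2C were among the 4 with a peak in WT alone (3.30 in random lists). Among the p53 targets, ZMAT3 with 5 peaks, TP53INP1 with 3, CCNG1 with 3 and SESN1 with 2 were among the 5 with a peak in WT alone (3.49 in random lists), and PLK3 had a peak in KO alone (3.28). In the checkpoint group BRCA2, MDC1, RAD1 and CHEK2 were among the 7 in WT alone (4.50 in random lists), and BRCA1, TIPIN, ATR and ETAA1 were the 4 in KO alone (4.07). Heat shock and unfolded protein response genes numbered 15 of 19 in WT and 19 of 19 in KO, with BAG3, XBP1, HSP90AB1 and HSPB1 in KO alone (2.91 in random lists). XBP1, HSP90AB1 and HSPB1 each rested on 1 KO minus UV peak, of 117, 100 and 100 bases. The 68.9% of KO minus UV peaks with an overlap in WT minus UV compared with 25.8% after random placement.

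The lists with UV were compared between the genotypes in the same way. Of the WT plus UV peaks, 7880 (51.0%, 50.2 to 51.7) overlapped no KO plus UV peak, and of the KO plus UV peaks 1826 (19.3%, 18.5 to 20.1) overlapped no WT plus UV peak. On transcripts with a peak in both lists, 25.5% of the WT plus UV peaks had no overlap. Among checkpoint genes, BRCA1, RNF168, NBN and ATRIP were of the 12 with a peak in WT alone (8.72 in random lists, percentile 90.3), and ATM had a peak in KO alone. CUL4B, ERCC6, UVSSA and RPA3 were of the 5 excision repair genes in WT alone (7.25 in random lists), and USP1, POLI and RAD18 were the 3 of translesion synthesis (4.75), while RAD23B and the DNA-protein crosslink protease SPRTN had a peak in KO alone. The 8 chromatin regulators in WT alone (9.02 in random lists) included KDM6A, ARID2, SETD2 and BPTF. Outside the central 95% of random lists were ZNF genes, with 109 in WT alone against 80.8 and 6 in KO alone against 13.7, heat shock genes, with 0 in WT alone against 5.83, and immediate early genes, with 1 in WT alone against 5.63. The WT list came from 4 IP libraries and the KO list from 2.

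The question of whether UV-gained peaks depend on METTL3 was addressed with the 4632 peaks found in WT plus UV and not in WT minus UV. Of these, 2256 (48.7%, 47.3 to 50.1) overlapped no peak of either KO list. Among the 10833 WT plus UV peaks shared with WT minus UV the value was 16.4% (15.7 to 17.1). The mirror set, 3133 WT peaks found without UV and not with it, gave 56.7% (54.9 to 58.4). The difference, UV-gained minus UV-lost, was -7.98 percentage points (-10.2 to -5.72). In KO cells, 743 of 2139 UV-gained peaks (34.7%) and 1806 of 6516 UV-lost peaks (27.7%) overlapped no WT peak. Among KO peaks shared with the other KO list, the values were 7.68% in KO plus UV and 7.44% in KO minus UV. At the gene level, 666 genes carried a peak in WT plus UV and in no other list, 421 in WT minus UV, 405 in KO minus UV and 167 in KO plus UV. Peaks gained in WT cells had a median width of 170 bases and shared ones of 198.

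The transcripts of the m6A machinery carried peaks of their own. METTL3 (chromosome 14, 21498138 to 21511340) had peaks at bases 13 to 180 and 500 to 725 of its transcript in WT minus UV, and at 12 to 180 and 497 to 725 in WT plus UV. In KO minus UV it had a peak at 501 to 662, and in KO plus UV peaks at 1 to 180 and 494 to 720. A peak list does not measure the level of a transcript or protein, so the knockout could not be checked from it. Of 19 members with a peak in any list, 15 carried a peak in WT minus UV, 16 in WT plus UV, 17 in KO minus UV and 12 in KO plus UV. The methyltransferase subunit VIRMA carried 4, 4, 5 and 0 peaks, METTL14 1, 0, 1 and 0, WTAP 1, 0, 1 and 1, ZC3H13 0, 1, 0 and 0, and RBM15 0, 0, 1 and 0. RBM15B, an adaptor of the methyltransferase (chromosome 3, 51391285 to 51397908), carried 3 peaks in each UV list and 0 in each list without UV. HNRNPA2B1 carried 0, 2, 2 and 1 peaks. CBLL1 carried 2 peaks in each list and METTL16, another m6A methyltransferase, 1, 1, 3 and 1. The demethylase FTO carried 2, 2, 2 and 1 peaks and ALKBH5 1, 1, 2 and 0, and among the readers YTHDF1 carried 1, 2, 2 and 2, YTHDF2 1, 1, 2 and 1, YTHDF3 1, 2, 2 and 0, YTHDC1 3, 4, 2 and 3, and YTHDC2 3, 1, 3 and 0. IGF2BP2 carried 3, 3, 3 and 1 peaks and HNRNPC 2, 2, 1 and 2, while METTL5, IGF2BP1 and IGF2BP3 had no matched peak.

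**Figure D4:**
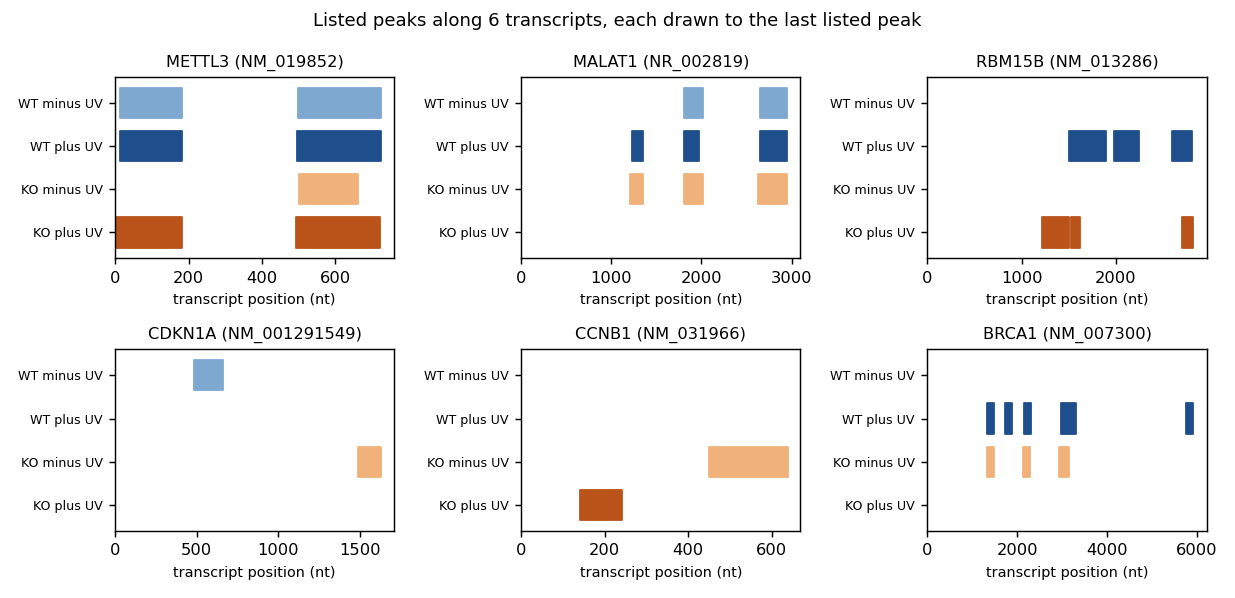
Listed peaks (bars) along the transcripts of METTL3, MALAT1, RBM15B, CDKN1A, CCNB1 and BRCA1 in bases from the first base of each transcript, with a line of bars per list. METTL3 carries a peak starting at 494 to 501 in all 4 lists, RBM15B carries peaks in the UV lists alone, and the CCNB1 peaks of the KO lists, at 450 to 637 and 141 to 240, do not overlap.

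Immediate early genes, which are induced within minutes of many stimuli, were the group that most often held a peak in every list. Of 18 members, 15 carried a peak in all 4, against a mean of 7.13 in random lists. NR4A1 carried 2, 2, 3 and 3 peaks and JUN 2, 1, 2 and 1. Zinc finger ZNF genes were the opposite. Of 262 with a peak in any list, 179, 197, 162 and 94 carried a peak in the 4 lists, and 63 in every list against 113.1 in random lists. In WT cells 45 of the 179 ZNF genes with a peak without UV were lost with UV, against 21.6 of 199.2 in random lists, and 63 were gained, against 43.5 in random lists, which had fewer genes left to gain a peak. Among long noncoding RNAs, MALAT1 carried 2, 3, 3 and 0 peaks, NEAT1 0, 1, 3 and 3, and NORAD 5, 4, 3 and 2. Osteoblast genes with a peak numbered 9, 8, 8 and 7 of 10, and RUNX2, the lineage's main transcription factor, carried 3, 0, 3 and 0 peaks. Collagen and matrix genes numbered 16, 17, 17 and 16 of 19, with COL4A1 in WT plus UV alone. Genes with the ribosomal protein prefixes numbered 21, 21, 25 and 20 of 29, and without the kinases that share the prefix 15, 15, 19 and 15 of 21. Of the markers of other cell types, CD68 was the only blood marker with a peak, in WT plus UV, 3 epithelial markers carried a peak in some list (CLDN4, EPCAM and KRT8), and 3 neuronal markers did (NEFL, SLC17A7 and RBFOX3). These percentiles and means describe the lists and are not tests between conditions: of 240 percentiles computed, 34 lay outside the central 95% of the random lists, where 12 would by chance if they were independent.

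**Figure D5:**
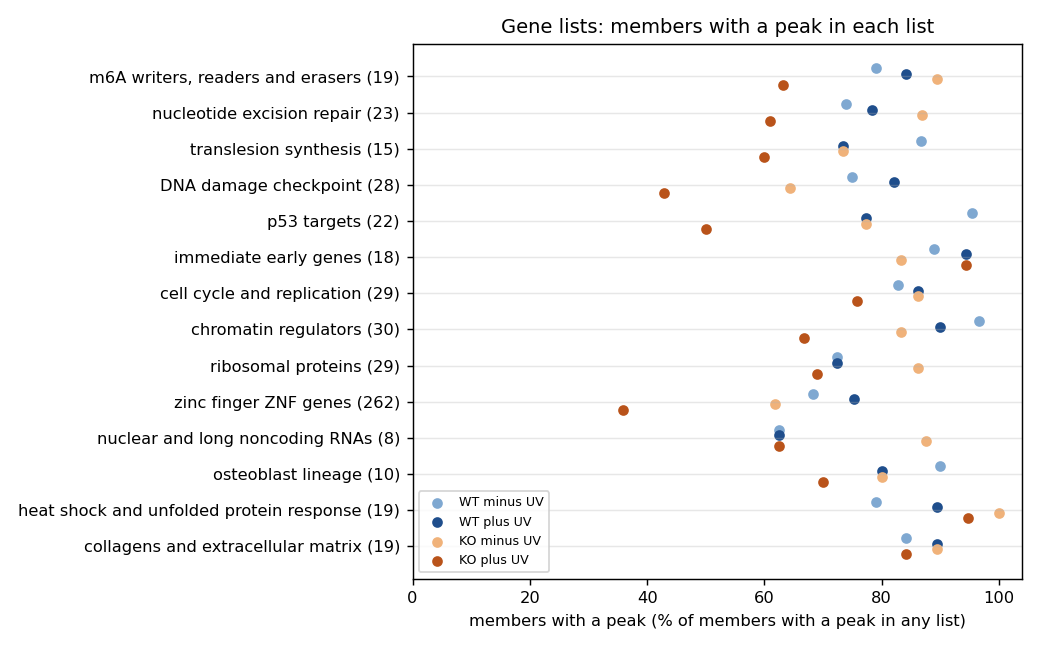
Percent of the members of 14 gene lists that carry a peak in each peak list (horizontal axis), out of members with a peak in any list, whose number follows each name. Immediate early genes hold 17 of 18 in KO plus UV, and ZNF genes 94 of 262.

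Peaks that start within the first 100 bases of the transcript made up 12.7% of the WT minus UV list (12.1 to 13.2), 13.7% of WT plus UV (13.1 to 14.2), 11.8% of KO minus UV (11.2 to 12.3) and 14.3% of KO plus UV (13.6 to 15.02). The difference with UV was 1.003 percentage points in WT cells (0.230 to 1.77) and 2.54 in KO cells (1.66 to 3.43). On transcripts with a peak in every list it was 0.399 in WT (-0.597 to 1.39) and 1.27 in KO (0.264 to 2.28). Of these 3971 transcripts, those with a peak starting there numbered 1018 without UV and 1090 with it in WT, and 986 and 946 in KO. All peaks on them numbered 8305 and 8612 in WT, and 8668 and 7482 in KO. The KO share thus rose although fewer transcripts held such a peak, because the number of all peaks fell further. Of WT peaks gained with UV, 15.3% started there, and of WT peaks lost with UV, 11.4%. This measure was added after the lists had been examined.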

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

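Every test in this part was chosen after the result it bears on had been seen, except the comparison by peak width.

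UV went with opposite differences in the 2 genotypes, and none of these could be tested between them, since each condition has 1 list and KO plus UV has 2 IP libraries against 3 or 4 elsewhere. The number of peaks differed by 10.6% in WT and -31.6% in KO, plus over minus UV. The number of genes with a peak differed by 11.7% in WT and -20.8% in KO, and by 5.03% and -3.06% once the other lists were thinned at random to the size of KO plus UV. Thinning fixes the number of peaks and removes them independently, so it does not correct for the number of IP libraries. Of transcripts with at least 5 KO minus UV peaks, 26.5% lacked a KO plus UV peak, against 1.63% expected if peaks were lost independently. An excess over that expectation was not particular to KO plus UV. Of transcripts with at least 5 WT minus UV peaks, 4.97% lacked a WT plus UV peak, against 0.0344% expected. For a KO minus UV peak the values were 4.66% and 0.221%. Mean peak width differed by 1.83% in WT and -4.48% in KO. The share of peaks on noncoding transcripts differed by 8.26% in WT and -19.6% in KO, relative to the share without UV. The WT shares behind it, 2.29% (2.05 to 2.55) and 2.48% (2.24 to 2.73), have overlapping intervals, so that no opposite direction is shown beyond counting error. Members with a peak moved in opposite directions in 8 gene lists, of which 4 kept both directions in the thinned lists. Before thinning, these were the m6A machinery (15 and 16 in WT, 17 and 12 in KO), the checkpoint list (21 and 23, 18 and 12), ZNF genes (179 and 197, 162 and 94) and epithelial markers (1 and 2, 2 and 1). After thinning, the means were 12.3 and 12.8 in WT and 14.4 and 12 in KO for the m6A machinery. They were 17.0 and 18.6, 15.2 and 12 for the checkpoint list, and 144 and 147, 133 and 94 for ZNF genes. For epithelial markers they were 0.86 and 1.64, 1.64 and 1. Excision repair, cell cycle, heat shock and matrix genes did not keep both directions. Random lists moved in the same directions, with means of 14.5 and 16.1 in WT and 14.3 and 11.2 in KO beside the m6A machinery, and of 21.1 and 23.4, 20.7 and 16.2 beside the checkpoint list. The epithelial counts rest on 3 genes. A further 365 genes carried a peak with UV alone in WT and without UV alone in KO, BRCA1 and TIPIN among them, and 67 genes showed the reverse. No chance level was computed for these counts. The first draws on 1661 genes gained in WT and 2275 lost in KO, and the reverse on 823 lost and 824 gained. The sizes of these sets alone would make the first count the larger, so the difference between the counts shows no opposite response of genes.

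KO cells without UV held about as many peaks as WT cells, mostly in the same places, although METTL3 is the main m6A methyltransferase. Uniform chance placement along the same transcripts was argued against, since 68.9% of KO peaks overlapped a WT peak and the highest of 5 random placements reached 26.1%. A preference of peaks for the same part of a transcript was not covered by that placement. Methylation next to the cap of the listed transcripts, which METTL3 does not make, was argued against as the main source, since 11.8% of KO peaks started within 100 bases of the transcript start, with an upper limit of 12.3%. Starts of other transcripts of a gene could not be judged, since all but 2 genes were listed with 1 transcript. Mislabelled KO libraries cannot be told apart from a true KO: the Jaccard percentage of the lists without UV was 51.6, between the WT pair (57.8) and the KO pair (45.9), and the lists hold no expression values. Residual METTL3 activity, another methyltransferase and antibody binding to unmodified RNA stay open as untested explanations.

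UV-gained WT peaks lacked a KO peak more often than peaks found in both WT lists, by 32.3 percentage points. Such a gap was not particular to them. UV-lost WT peaks lacked a KO peak in 56.7%, against 16.4% of shared ones. In KO cells, peaks lacked a WT peak in 34.7% of those gained with UV, against 7.68% of shared ones. For KO peaks lost with UV the values were 27.7% and 7.44%. Absence of the whole transcript from the KO lists was argued against as the whole cause, since the gap was 23.3 points (21.6 to 24.9) on transcripts with a KO peak. Turnover of narrow, weakly supported peaks may contribute and stays open: among peaks at or above the median width of 189 bases the gap was 26.8 points (24.3 to 29.3), and the interval spans the 5-point reduction set beforehand as the limit. UV-specific METTL3-dependent methylation would place gained peaks above lost ones, and the difference was -7.98 points (-10.2 to -5.72). Since the gained set comes from 4 IP libraries and the lost set from 3, this cannot exclude such peaks among those gained.

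Of the transcripts with at least 5 KO minus UV peaks, 26.5% (22.2 to 31.3) held no KO plus UV peak. Fewer IP libraries behind KO plus UV could act on whole transcripts, for example through a minimum of coverage: 31.7% of the transcripts with at least 5 WT minus UV peaks were absent there, against at most 4.97% in the lists of 3 or 4 libraries. Fewer transcripts of long genes with UV in KO cells is a candidate explanation as well, since the share absent was 18.9 points higher (12.4 to 25.3) in the longest than in the shortest quintile of genes. For WT minus UV transcripts absent from WT plus UV this difference was 3.49 points (0.0354 to 7.08), below that interval, and for the reverse WT pair (-2.70 points, -6.82 to 1.39) and WT minus UV against KO minus UV (-1.74, -6.16 to 2.65) the interval included 0. As a ratio, which allows for the lower share absent in WT cells, the longest over the shortest quintile was 2.12 (1.61 to 2.80) in KO cells and 1.92 (1.001 to 3.70) for WT minus UV against WT plus UV, so that whether the KO gradient stands apart depends on the scale. WT plus UV transcripts absent from KO plus UV, where both lists had UV, gave 12.1 points (5.38 to 18.7) and a ratio of 1.45 (1.18 to 1.80). These 2 explanations cannot be told apart, because KO plus UV is the only list with 2 libraries. The lists hold no expression values with which to check for fewer transcripts, and the cells were collected after 2 min.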

How the results depend on the processing

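The alternatives by thinned lists, minimum width, transcripts in both lists, KO minus UV alone and copy-numbered transcripts, and those of the transcript start, were chosen after the data were examined. No paired analysis was possible because each condition has 1 list for all its replicates, and for the same reason no replicate could be left out. Alternatives that need a score (the stronger 50% of a list, lists shortened by score), genomic exons (the whole genomic span, gene by exon overlap), chromosomes of the peaks, coding regions or sequence were not run. In the 18 alternatives for the number of peaks, the 12 for genes with a peak and 62 of the 64 for gene lists, the count stayed within 1.5 times its value. The exceptions, under thinning, were ribosomal proteins in WT plus UV (13.8 in place of 21) and neuronal markers in WT plus UV (1.26 in place of 2). At equal list size the difference with UV in genes with a peak was 5.03% in WT and -3.06% in KO, in place of 11.7% and -20.8%. This setting fixes the number of peaks and is no correction for the number of IP libraries.

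The shares without an overlap are given in the order WT plus UV without WT minus UV, KO plus UV without KO minus UV, WT minus UV without KO minus UV, and WT plus UV without KO plus UV. They were 30.0%, 22.6%, 32.1% and 51.0%. With an overlap of 50% of the shorter peak they were 31.8%, 24.9%, 33.9% and 52.6%, and of both peaks 35.5%, 30.4%, 38.5% and 56.1%. For genes they were 20.8%, 14.9%, 22.0% and 37.6%, on transcripts with a peak in both lists 17.3%, 13.4%, 18.3% and 25.5%, and for peaks of at least 150 bases 24.9%, 16.9%, 27.03% and 47.2%. Merging within 100 bases left the first 3 within their intervals and gave 50.1% for the last. Thinned lists gave 51.8%, 46.4%, 52.9% and 51.0%: random thinning removes partners from both lists, except from KO plus UV, which is kept whole, so that it raises the first 3 by construction. UV-gained WT peaks without a KO peak (48.7%) were 52.9% with 50% of both peaks, 40.1% for genes, 32.6% on transcripts with a KO peak, 44.1% at 150 bases, 42.8% in thinned lists and 58.1% against KO minus UV alone. Apart from thinning, the order of the 4 shares was the same under each of these alternatives; beyond the constructions named, the cause was not tested. The UV difference in the share of peaks at the transcript start stayed above 0 in its 8 alternatives. In WT cells its interval included 0 on transcripts in all 4 lists (0.399 points) and for peaks of at least 150 bases (0.706 points). This share also depends on the number of all peaks, and the cause was not tested. With the 50-base window on transcripts in all 4 lists, which is outside those 8, the KO interval included 0 as well (0.755 points, -0.125 to 1.64). The depth behind each peak is unknown and limits what the absence of a peak shows.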

Other observations

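The percentiles in this part and the lists they refer to were looked at after the gene counts had been seen, and none is a test between conditions.

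Genes with a peak in both KO lists and in no WT list were most frequent, relative to random lists, in the cell cycle and ribosomal groups. Of 29 cell cycle genes 4 were of this kind, against a mean of 0.619 in random lists (percentile 99.8): the mitotic cyclins CCNB1 and CCNB2, the mitotic kinase PLK1 and the proliferation marker MKI67. Their peaks spanned 100 to 221 bases, and those of CCNB1 did not overlap between the KO lists. Ribosomal protein genes, without the kinases that share their prefix, also gave 4 of 21, against 0.664 (percentile 99.8): RPLP0, RPLP1, RPS3A and RPS7, all among the most abundant mRNAs of dividing cells. Single members were of this kind in 4 other lists: HSPB1 (heat shock, 0.403 in random lists), SPRTN (translesion synthesis, 0.313), RAD23B (excision repair, 0.472) and OIP5-AS1 (long noncoding RNAs, 0.188). Each of the 19 heat shock genes with a peak carried one in KO minus UV, against a mean of 13.8 (percentile 99.9). XBP1 and HSPB1 had no WT peak, so they entered the 19 through the KO lists alone. ZNF genes gave 0 of 262, against 4.92 (percentile 0.405).

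Genes with a peak in both WT lists and in no KO list lay within the range of random lists in the damage response groups. CHEK1, CHEK2, RAD1 and H2AX of the checkpoint list carried a peak in both WT lists and in no KO list, against a mean of 1.95 (percentile 91.4), as did TP53I3, ZMAT3 and TP53INP1 of the p53 targets, against 1.52 (percentile 87.4). Excision repair gave 1, against 1.68 (percentile 33.4), and translesion synthesis 1, against 1.11 (percentile 50.7). MAT2A, whose mRNA is a known substrate of METTL16, carried 2 peaks in each list. POLH and POLK, translesion polymerases, had no matched peak in any list. The genes CHEK1, H2AX, TP53I3, RPS3A, MAT2A, POLH and POLK were outside the rule for named genes and were chosen after their values were seen.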
